A study of Homo sapiens with 6 samples.

How the data were processed

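Poly(A) RNA was sequenced from 8505C anaplastic thyroid cancer cells 24 h after siRNA treatment, in 3 control (NC) and 3 siPOLR1F libraries. Per the labels' protocols, cells grew in medium with 10% fetal bovine serum, 1 µg of total RNA entered each library and reads were paired, with a length of 150 bases. Per the submitters' processing notes, fastp, HISAT2 and StringTie were used with the GRCh38 (hg38) build; versions, gene annotation, strand setting and treatment of reads with several matches are not given in the sources used here. All libraries carry the same batch label. Groups and replicate numbers came from the labels.

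The authors deposited 1 table of 33539 Ensembl genes with a count and an FPKM value per gene and library. The deposited counts are whole numbers and were used as deposited. The deposited FPKM (a count scaled by gene length and library size) were checked against the counts: in 11428 genes with over 200 counts in each library, the ratio of FPKM to count deviated from a single factor per library by 0.0202% (median) and at most 2.10%. All 6 count and 6 FPKM columns matched a sample, each row named a gene, and gene names, coordinates and annotated terms were taken from the table. Of its identifiers, 31829 were in GENCODE release 29, and 72.2% of those had the same start, so the authors' annotation was another release. Transcript sequences came from GENCODE 29. Without a stated strand setting, reads of overlapping genes on either strand may be divided between them.

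Differential expression was tested on counts with edgeR 4.0.16 (TMM factors, glmQLFit and glmQLFTest; R 4.3.3), two-sided, in genes with a mean FPKM of at least 0.5 over the 6 libraries. These 13564 genes held 99.4% of the counts, and the biological coefficient of variation was 0.137. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. The plan, fixed before the data were examined, named limma on log2(FPKM + 1) unless the table held counts, in which case edgeR was the main test and limma an alternative; the plan wrote the set test on log2(FPKM + 1), and it was moved to the counts by the same clause. Gene sets were tested with camera (limma 3.58.1) at a preset correlation of 0.01, for 24 of 28 lists fixed beforehand with at least 5 tested members and for annotated terms with 10 to 500 members, adjusted within each kind of term, beside an estimated correlation and fry. Of 816 list symbols, 801 were in the table. Depth was alike between libraries, from 60576788 to 63038378 counts. Pairwise chi-square tests of the counts found no libraries within sampling noise of each other.

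The rule for named genes took POLR1F and F2R, the 10 genes with the largest rise and the 10 with the largest fall among those past the test with a mean FPKM of at least 1 and no overlap between the groups, and up to 4 members per list with the smallest adjusted p, or the 2 most abundant where none passed. Some of the genes this rule names are not used here. On counts simulated for this comparison from 13564 genes, of 50 genes each the test recovered 68% at a log2 change of -1, 30% at -0.5, 56% at 0.5 and 76% at 1. Of its 126 calls, 11 (8.73%) were false, above the nominal 5%, and camera called the planted list and 0 of 20 random lists. Genes were simulated independently of each other, whereas the estimated correlation was 0.496 for ribosome biogenesis and 0.576 for mitochondrially encoded genes. The random lists therefore do not show how often camera at the preset correlation calls correlated lists falsely.

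Each heptamer was scored as present or absent in the longest annotated 3′ UTR (at least 50 bases) of 11132 tested genes. The log2 fold change was regressed on its presence with UTR length and GC content in the model. Values adjusted for length and GC content were clipped at the outer 1% on each side. A planted heptamer was ranked first. Site groups were compared by two-sided permutation tests with 100000 draws of genes without replacement (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Their p-values treat genes as independent and do not measure the spread between libraries. The sequence of a widely sold control siRNA was taken from general knowledge, as the labels name no siRNA sequence.

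Alternatives were DESeq2 1.42.0, other expression filters, other scalings, limma on log2(FPKM + 1) with pseudocounts of 1, 0.1 and 0.01 and variants of its variance model, the replicate number as a block, and leaving out each library. DESeq2 size factors in edgeR, library size alone, robust dispersions and leaving out genes with a heptamer site were added after the data were seen.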

Results

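Gene expression was measured by poly(A) RNA sequencing in 8505C cells, an established line of anaplastic thyroid cancer, the undifferentiated and most aggressive form of thyroid carcinoma. Cells received either a negative control siRNA (NC, 3 libraries) or an siRNA against POLR1F (siPOLR1F, 3 libraries) for 24 h. POLR1F is a subunit of RNA polymerase I, the enzyme that transcribes the ribosomal RNA genes. The deposited counts summed to between 60576788 and 63038378 per library. Mitochondrially encoded genes took 5.15%, 4.93% and 4.99% of the counts in the NC libraries and 4.85%, 4.41% and 4.32% in the siPOLR1F libraries. The labels do not say whether the 3 libraries of a group came from separate cultures. The p-values of single genes therefore measure the spread between these libraries, which may be technical. Camera with a preset correlation compares the members of a list with other genes. Its p-values do not measure the spread between libraries for the list as a whole. The comparison asked which genes respond to loss of POLR1F, and the series title names proliferation, stemness, the thrombin receptor F2R and p38 MAPK signalling as its subjects.

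POLR1F (ENSG00000105849, GRCh38 chromosome 7, 19695461 to 19709037, minus strand) was lower in each siPOLR1F library than in each NC library. Its counts were 2446, 2246 and 2095 in NC and 575, 395 and 413 in siPOLR1F. The FPKM was 8.28 ± 0.592 (SD, n = 3) in NC and 1.67 ± 0.368 (SD, n = 3) in siPOLR1F, a log2 fold change of -2.30 (SE 0.15; edgeR adjusted p = 9.76e-05) or a 79.6% lower level. F2R (ENSG00000181104, chromosome 5, 76716126 to 76735770, plus strand), which encodes the receptor cleaved by thrombin, was lower as well. Its FPKM was 8.86 ± 1.14 (SD, n = 3) in NC and 3.90 ± 0.822 (SD, n = 3) in siPOLR1F, with a log2 fold change of -1.18 (SE 0.15; edgeR adjusted p = 0.00181). For both genes the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. A linear model per gene without shared variance gave F2R an adjusted p of 0.0551, and over all alternatives its adjusted p lay between 4.61e-14 and 0.0551.

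**Figure D1:**
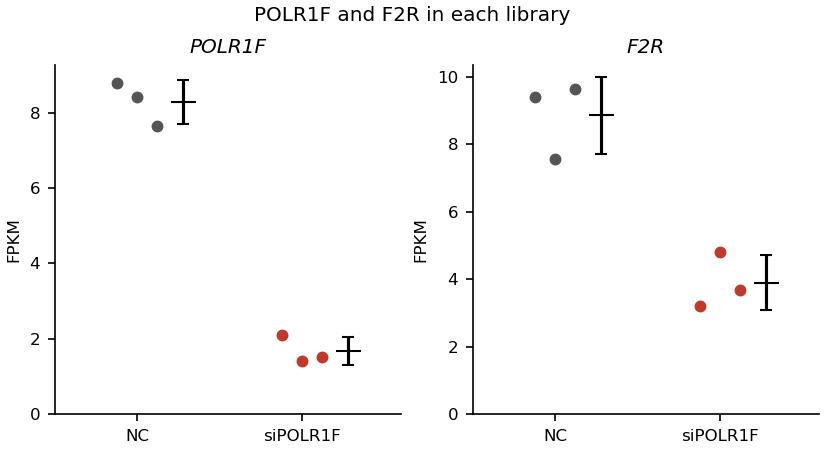
FPKM of POLR1F and F2R (vertical axes) in the 3 NC and 3 siPOLR1F libraries. Points are libraries, and the bars beside them give the mean and SD of each group; the 3 siPOLR1F libraries lie below the 3 NC libraries for both genes.

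Of 13564 genes tested, 1391 were higher and 942 lower in siPOLR1F by the edgeR quasi-likelihood test at an adjusted p below 0.05. Most changes were small, with a median log2 fold change of 0.41 among the higher and -0.39 among the lower genes, and 56 higher and 35 lower genes reached an absolute log2 fold change of 1. NOLC1 (ENSG00000166197, chromosome 10, 102152176 to 102163871), a nucleolar chaperone of small nucleolar ribonucleoproteins, rose from 19.0 ± 1.46 to 57.2 ± 3.03 FPKM (SD, n = 3 each), 3.02 times the NC level (edgeR adjusted p = 5.91e-05). TPM4 (ENSG00000167460, chromosome 19, 16067021 to 16103002), an actin-binding tropomyosin, rose from 26.8 ± 4.77 to 81.7 ± 1.30 FPKM. The dynein adaptor BICD2 rose by 1.48 on the log2 scale, the cyclin-dependent kinase CDK14 by 1.43, EMC6, a subunit of the membrane protein insertase of the endoplasmic reticulum, by 1.40 and the cytokine IL24 by 1.37. The growth factor BMP2 rose by 1.69, and its edgeR adjusted p was 0.0152 with all libraries and 0.0547 without NC replicate 3, within a range of 1.44e-06 to 0.137 over its alternatives. Among the lower genes, ARL6IP6 had a log2 fold change of -1.41, the interferon-induced IFIT1 of -1.41 and IFIT3 of -1.16, GOLM2 of -1.30 and the epidermal protein KPRP of -1.12. The pseudogenes SMG1P6 (1.96) and RPSAP52 (1.65), GSTT2 (-1.97) and RN7SL2 (-1.78) also met the naming rule, but share sequence with close copies and are uncertain. SMG1P6 failed the edgeR test without any NC library, siPOLR1F replicate 1 or replicate 3 (adjusted p from 0.0552 to 0.134; 0.0121 to 0.2505 over its alternatives). GSTT2 failed without NC replicate 1 or 3 or siPOLR1F replicate 1 or 2 (0.0513 to 0.0732; 3.97e-04 to 0.211 over its alternatives), and RN7SL2 without siPOLR1F replicate 2 (0.0670) or 3 (0.0815; 1.68e-05 to 0.159 over its alternatives). RPSAP52 also overlaps HMGA2, ARL6IP6 overlaps a neighbouring gene, CDK14 overlaps CLDN12, EMC6 overlaps a readthrough locus, and the IFIT genes overlap LIPA, so that reads may be divided between them.

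**Figure D2:**
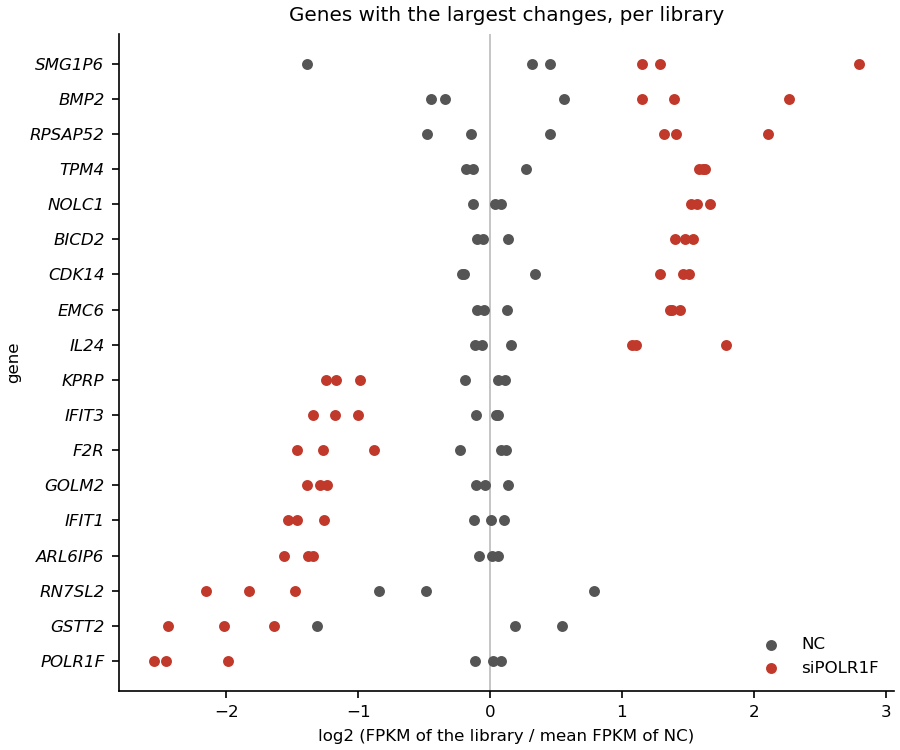
Log2 ratio of each library's FPKM to the NC mean (horizontal axis) for genes among the 10 with the largest rise and the 10 with the largest fall. Points are libraries, 3 per group; for each gene the siPOLR1F points lie on a single side of the NC points, and the spread is widest for SMG1P6, GSTT2 and RN7SL2.

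The heptamer TCGGAGA occurred in the coding sequence or 3′ UTR of TPM4, NOLC1, BICD2 and CDK14, which are 4 of the 8 genes searched among the 10 with the largest rise, against 9.45% of all 11132 genes searched. It also occurred in 2 of the 8 genes searched among those with the largest fall besides POLR1F, IFIT1 and KPRP. Another heptamer, CCGACTT, occurred in ARL6IP6, GOLM2 and KPRP, and in 13.5% of the lower genes searched against 6.49% of all genes searched. Both heptamers were taken up after a scan of 3′ UTRs against these same fold changes. There CCGACTT ranked first for a fall and TCGGAGA second for a rise. Their excess among changed genes therefore follows in part from that choice and is not an independent test. F2R holds no copy of CCGACTT but has a hexamer of it in the 3′ UTR. Among the genes described below, TCGGAGA also occurs in GNA11, DTL and DLC1, which rose, and in FN1, which fell. CCGACTT occurs in FJX1 and HSPG2, which fell, and in XPC, NOTCH1 and NOP14, which rose. The counts of changed genes varied with the libraries used. Without NC replicate 3 they were 877 higher and 539 lower, without siPOLR1F replicate 1 they were 813 and 444, without replicate 2 they were 898 and 517, and without replicate 3 they were 730 and 423.

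More genes that make ribosomes rose than fell. Of 55 ribosome biogenesis genes tested, 20 rose, 1 fell and 34 did not pass the test; adjusted over the list alone, 33 rose and 1 fell. Besides NOLC1, the rises included TCOF1, which acts in ribosomal DNA transcription (log2 fold change 0.80), POLR1B, a core subunit of RNA polymerase I (0.55), and NOP14, a factor of small-subunit maturation (0.57). NOLC1 holds TCGGAGA in the 3′ UTR, and TCOF1, POLR1B, NOP14 and UBTF hold it in the coding sequence. Without genes that hold either heptamer or lack an annotated 3′ UTR, 16 of 45 rose and 1 fell (camera adjusted p = 1.61e-06). Genes with only a hexamer stayed in. Of all genes with only a TCGGAGA hexamer in the coding sequence, 18.5% were higher, against 8.42% of those without a site there. The filter therefore does not separate the rise of this list from such sites. With all 55 the list ranked higher by camera with a preset correlation (adjusted p = 5.06e-11), and had an adjusted p = 0.438 with an estimated correlation. Of 15 snoRNA host genes, which carry small nucleolar RNAs in their introns, 9 rose and none of the 15 fell; adjusted over the list alone, 13 rose. SNHG12 (0.58), ZFAS1 (0.64) and GAS5 (0.31) were among them, and camera gave an adjusted p = 7.44e-05, or an adjusted p = 0.438 with an estimated correlation. Of 21 subunits and factors of RNA polymerase I, 5 rose, among them POLR1B and UBTF (0.48), and 1 fell, POLR2K (-0.33). POLR2K did not pass without NC replicate 3 (edgeR adjusted p = 0.0501), siPOLR1F replicate 1 (0.0554) or replicate 3 (0.0608, the highest of its alternatives, which began at 8.41e-04). Adjusted over the list alone, 6 rose and 1 fell. The camera adjusted p for this list was 0.0429, and an adjusted p = 0.499 with an estimated correlation; fry gave 0.0570. This call ended without NC replicate 1 (camera adjusted p = 0.142), without NC replicate 3 (0.0826) and without siPOLR1F replicate 3 (0.0695). It also ended without genes that hold either heptamer or lack an annotated 3′ UTR (0.410). That was the highest of its alternatives at the preset correlation, which began at 0.0034. None of the 78 cytosolic ribosomal protein genes passed the edgeR test; the most abundant, RPS2, was at 857 ± 40.1 FPKM in NC and 867 ± 42.6 in siPOLR1F (SD, n = 3), and RPS12 at 793 ± 23.3 and 788 ± 15.7. Their list was not called (camera adjusted p = 0.109), but passed without NC replicate 1 (0.0380) and without siPOLR1F replicate 2 (0.0221). Its alternatives at the preset correlation gave 0.00914 to 0.656, and an estimated correlation 0.739.

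Cholesterol synthesis genes were mostly lower. Of 25 tested, 15 fell, 1 rose and 9 did not pass; adjusted over the list alone, 20 fell and 1 rose. The enzymes MSMO1 (log2 fold change -0.80), IDI1 (-0.63) and FDFT1 (-0.60) and the sterol carrier STARD4 (-0.76) fell; STARD4 moves sterols and does not make them. Camera gave an adjusted p = 5.06e-11, and an adjusted p = 0.438 with an estimated correlation. Of 30 hypoxia and glycolysis genes, 10 fell and 1 rose; adjusted over the list alone, 17 fell and 3 rose. LDHA, which makes lactate from pyruvate, went from 668 ± 3.38 to 542 ± 12.7 FPKM (SD, n = 3), and PFKFB4, a regulator of glycolysis, fell by 0.61. Other members of this list that fell act elsewhere, namely INSIG2 (-0.73), which restrains sterol synthesis, and LOX (-0.37), which cross-links collagen. Its camera adjusted p was 7.44e-05, and an adjusted p = 0.438 with an estimated correlation.

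Genes of p38 MAPK, protease-activated receptor and ERK signalling included rises and falls, and most did not pass the test. Of 34 p38 MAPK pathway genes, 5 rose and 3 fell, the same numbers when adjusted over the list alone. MKNK2, a kinase that phosphorylates the translation factor eIF4E, rose from 17.9 ± 1.33 to 35.6 ± 0.730 FPKM (SD, n = 3), the transcription factor gene ELK4 rose by 0.64 and the kinase RPS6KA4 by 0.40, while the kinase MAP3K20 fell by 0.39 on the log2 scale. MKNK2 and ELK4 hold TCGGAGA in the 3′ UTR. MAPK14, which encodes p38α and was chosen after its value was seen, had a log2 fold change of 0.14 (edgeR adjusted p = 0.223). The list was not called by camera (adjusted p = 0.293) but was called as higher by fry (adjusted p = 0.0116). Of 27 protease-activated receptors and their signalling partners, 3 rose and 5 fell, also when adjusted over the list alone. F2R fell, as did the tissue factor gene F3 (-0.29), and the G protein genes GNA11 (0.48) and GNA12 (0.38) rose; the camera adjusted p was 0.362. Of 26 ERK output genes, which are induced by the MAP kinase ERK, 6 rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone. EGR1 (1.07) and FOS (0.84), immediate-early transcription factors, the urokinase receptor PLAUR (0.36) and the ERK phosphatase DUSP5 (0.55) rose. Camera gave an adjusted p = 0.0129, and an adjusted p = 0.438 with an estimated correlation.

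Of 14 stemness markers tested, 2 rose and none of the 14 fell, while adjusted over the list alone 2 rose and 1 fell. NOTCH1 rose by 0.70, and CD44, a hyaluronan receptor, rose by 0.18. CD44 did not pass without NC replicate 2 or 3 or without any siPOLR1F library (edgeR adjusted p from 0.0509 to 0.0766, the latter the highest of its alternatives, which began at 0.0039). The list had a camera adjusted p of 0.370 and a fry adjusted p of 0.0428, higher. Of 7 thyroid differentiation genes, NKX2-1, a transcription factor of thyroid and lung, fell from 45.2 ± 3.02 to 27.5 ± 1.62 FPKM (SD, n = 3), and the other 6 did not pass; adjusted over the list alone 1 fell. The list had a fry adjusted p of 0.0428, lower, and a camera adjusted p of 0.103, and of 0.0380 without NC replicate 1, the lowest of its alternatives, which reached 0.911. Among 14 epithelial genes KRT8 alone passed (-0.25), and 1 fell when adjusted over the list alone. KRT8 did not pass without NC replicate 3 (0.0537), siPOLR1F replicate 1 (0.0660) or replicate 3 (0.0646), within edgeR, limma and DESeq2 adjusted p-values of 0.00141 to 0.112. The epithelial list had a camera adjusted p of 0.0755, and passed without NC replicate 2 (0.0366) and siPOLR1F replicate 2 (0.0493). Its alternatives at the preset correlation gave 0.0280 to 0.199, and an estimated correlation 0.438. Of 20 mesenchymal genes 2 rose and 2 fell, the latter being LOX and FN1 (-0.44), and adjusted over the list alone 2 rose and 3 fell; the camera adjusted p was 0.851. Of 30 extracellular matrix genes 6 fell, including MATN2 (-0.83), COL12A1 (-0.42) and HSPG2 (-0.51), and 2 rose, including LAMB3 (0.51); adjusted over the list alone 9 fell and 2 rose. Camera gave an adjusted p = 0.0129, and an adjusted p = 0.438 with an estimated correlation, and fry 0.0633. The camera call ended at a mean FPKM of at least 5, with edgeR (0.0789) and with limma (0.0636). Its alternatives at the preset correlation gave 0.00427 to 0.0789. Of 24 YAP and TEAD target genes 4 rose, including LATS2 (0.62) and DLC1 (0.46), and 5 fell, including FJX1 (-0.72), as also when adjusted over the list alone. Their median was 0.03, while their mean was -0.02 and the camera direction was lower, with an adjusted p of 0.851.

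Of 54 G2/M genes, 10 fell and 3 rose; adjusted over the list alone 13 fell and 3 rose. TACC3, a spindle protein, rose by 0.35. CKS2, a cofactor of cyclin-dependent kinases (-0.30), and KIF23, a kinesin of cytokinesis (-0.25), fell. CKS2 did not pass without siPOLR1F replicate 1, 2 or 3 (edgeR adjusted p = 0.0599, 0.0514 and 0.0518), nor KIF23 without replicate 2 or 3 (0.0614 and 0.0676). The adjusted p over all alternatives was 4.99e-04 to 0.0911 for CKS2 and 0.00123 to 0.0676 for KIF23. Camera gave the G2/M list an adjusted p = 5.19e-04, and an adjusted p = 0.438 with an estimated correlation. Of 43 G1/S genes 3 rose, including DTL (0.44) and TIPIN (0.70), and 1 fell; adjusted over the list alone 2 rose. The list had a camera adjusted p of 0.109, and of 0.0479 without siPOLR1F replicate 1. Its alternatives at the preset correlation gave 0.0034 to 0.302, and an estimated correlation 0.562. Of 22 replication-dependent histone genes H2BC5 rose (0.69) and H2AC11 fell (-1.03), and none of them passed when adjusted over the list alone. H2AC11 also failed the edgeR test without any library but siPOLR1F replicate 2 (adjusted p from 0.0641 to 0.104; 0.00845 to 0.142 over its alternatives), and H2BC5 without any but NC replicate 1 (0.0814 to 0.115; 0.00940 to 0.115 over its alternatives). Of 26 p53 target genes 5 rose, including XPC (0.48) and AEN (0.71), and 5 fell, including ZMAT3 (-1.11) and TNFRSF10B (-0.45), both with CCGACTT in the 3′ UTR; adjusted over the list alone 5 rose and 7 fell. The camera adjusted p was 0.304 for the p53 list and 0.605 for the histone list.

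Stress response genes were higher in part. Of 30 genes of the integrated stress response 8 rose and 2 fell, and 9 rose and 3 fell when adjusted over the list alone. TRIB3, a pseudokinase (0.71), PPP1R15A, which directs dephosphorylation of eIF2α (0.91), and the amino acid transporter genes SLC7A1 (0.58) and SLC3A2 (0.68) rose. Of 21 chaperones and factors of the unfolded protein response 7 rose and none of the 21 fell, and 8 rose when adjusted over the list alone, including XBP1 (0.50), P4HB (0.26) and CANX (0.29). P4HB holds TCGGAGA in the 3′ UTR. Camera gave adjusted p-values of 0.0131 and 0.0129 for these lists, with an adjusted p = 0.438 with an estimated correlation for both. Both calls ended without NC replicate 3 (camera adjusted p = 0.0512 for both). Their alternatives at the preset correlation gave 4.70e-04 to 0.0857 and 2.71e-05 to 0.130. Of 24 NF-kB and inflammatory genes 4 rose, also when adjusted over the list alone. The collagenase gene MMP1 went from 1196 ± 61.9 to 1807 ± 78.8 FPKM (SD, n = 3) and MMP3, a stromelysin, rose by 0.95. Camera gave an adjusted p = 0.0109, and an adjusted p = 0.438 with an estimated correlation. Without NC replicate 3 the camera adjusted p was 0.0609, within 9.17e-05 to 0.0972 over its alternatives at the preset correlation, and fry gave 0.0905. Of 26 interferon response genes 5 fell and none of the 26 rose, also when adjusted over the list alone. IFIT3 went from 3.65 ± 0.224 to 1.63 ± 0.195 FPKM (SD, n = 3), IFIT1 and IFIT2 (-1.06) fell alongside it, and PARP9 fell by 0.38. Camera gave an adjusted p = 5.19e-04, and an adjusted p = 0.438 with an estimated correlation. Of 15 mitochondrially encoded genes 2 fell, MT-ND4 (-0.19) and MT-ATP8 (-0.17), and 4 fell when adjusted over the list alone. MT-ND4 failed the edgeR test without NC replicate 1 or 3 or siPOLR1F replicate 2 or 3 (adjusted p from 0.0555 to 0.0823; 0.0102 to 0.633 over its alternatives), and MT-ATP8 without NC replicate 1 or 2 or siPOLR1F replicate 2 or 3 (0.0940 to 0.145; 0.0259 to 0.7103 over its alternatives). Camera gave an adjusted p = 0.0373, and an adjusted p = 0.562 with an estimated correlation, and fry 0.201. The call ended without NC replicate 1 (0.133), NC replicate 2 (0.0567), siPOLR1F replicate 2 (0.105) and siPOLR1F replicate 3 (0.161), within 7.15e-04 to 0.853 over its alternatives.

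**Figure D3:**
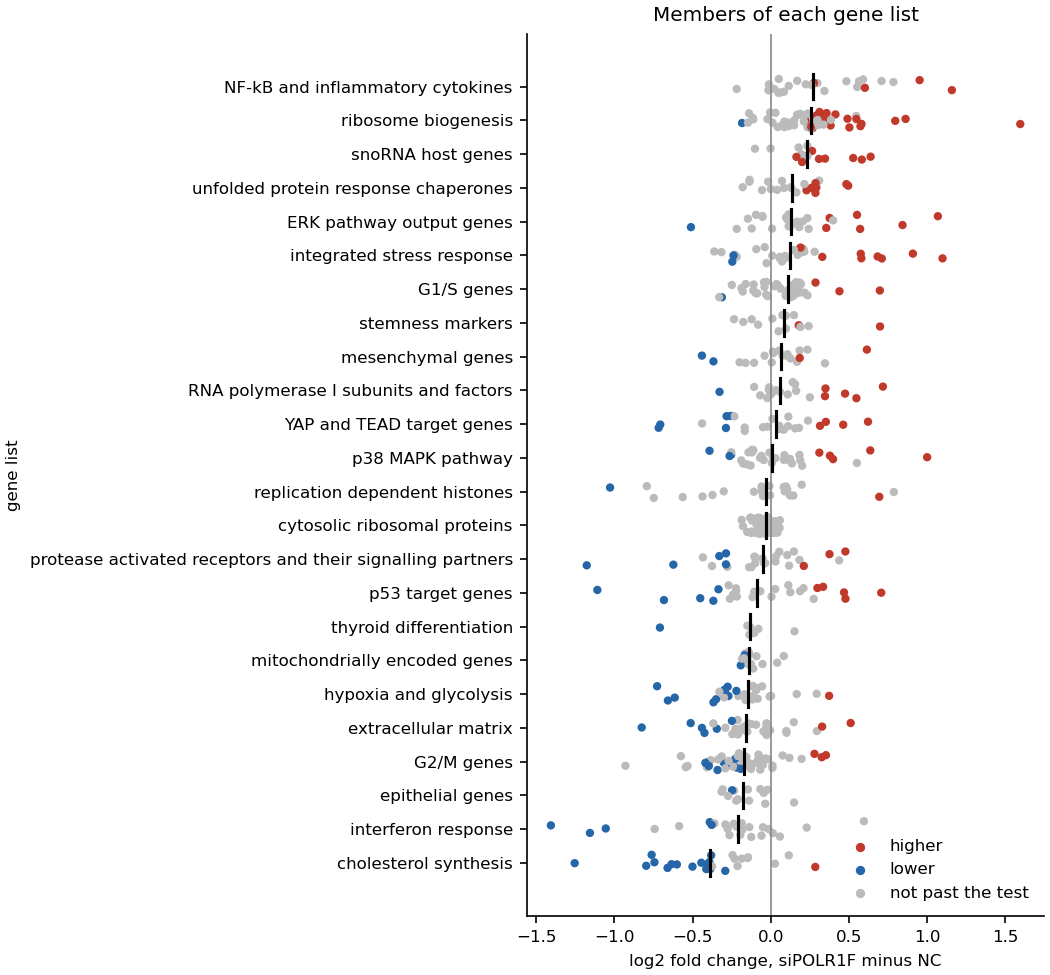
Log2 fold change, siPOLR1F minus NC (horizontal axis), of the tested members of each of 24 gene lists. Points are genes, red and blue where the edgeR adjusted p was below 0.05, and black lines are list medians, which run from -0.39 for cholesterol synthesis to 0.27 for NF-kB and inflammatory cytokines.

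Markers of other cell types were few, too few for a set test. Of the fibroblast markers COL1A1 (0.995 ± 0.327 and 0.847 ± 0.167 FPKM in NC and siPOLR1F; SD, n = 3) and COL3A1 (0.863 ± 0.0503 and 0.763 ± 0.0417) were tested and did not pass. Of 3 immune markers tested none passed; CD68 was at 9.33 ± 2.68 and 12.9 ± 2.89 and LYZ at 2.50 ± 0.650 and 2.17 ± 0.537. CD68 passed without NC replicate 1 (edgeR adjusted p = 0.0334, the lowest over its alternatives, which reached 0.439). Of 2 endothelial markers CDH5 fell from 5.65 ± 0.223 to 2.72 ± 0.671, and of 3 squamous keratinocyte markers KRT14 fell from 31.0 ± 2.09 to 22.9 ± 2.03, each also when adjusted over the list alone.

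Of 5930 annotated terms in the deposited table, camera called 27 as higher and 5 as lower, and called none of the 5930 with an estimated correlation, where the adjusted p of the called terms lay between 0.965 and 0.996. Steroid biosynthesis in KEGG was lower (18 genes, 10 fell; adjusted p = 1.22e-08) and ribosome biogenesis in eukaryotes higher (76 genes, 24 rose and 1 fell; adjusted p = 0.00978), both with an adjusted p = 0.965 with an estimated correlation. The Gene Ontology term for the large-subunit preribosome was higher (22 genes, 12 rose; adjusted p = 1.14e-04), as was that for the GBAF chromatin remodelling complex (13 genes, 7 rose; adjusted p = 1.83e-04), both with an adjusted p = 0.992 with an estimated correlation. The Reactome term for KRAB zinc finger genes, a family of transcriptional repressors, was higher (222 genes, 50 rose and 3 fell; adjusted p = 7.71e-04, or an adjusted p = 0.974 with an estimated correlation). KEGG complement and coagulation cascades was lower (22 genes, 7 fell and 2 rose; adjusted p = 0.0239, or an adjusted p = 0.965 with an estimated correlation). Without NC replicate 2, 67 terms were called.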

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

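The direction of POLR1F and F2R and the side of the threshold of POLR1F were kept in every alternative that tested them, POLR1F being untested where a mean FPKM of at least 5 was asked. A linear model without moderation gave F2R a log2 fold change of -1.02 with an adjusted p of 0.0551; there each gene's variance rests on its 6 libraries alone. No result changed sign while past the threshold.

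Numbers of genes past the threshold, higher and lower, were 663 and 313 with no filter on low values, 499 and 291 for limma with no filter, 508 and 342 for the linear model without moderation, 56 and 35 at an absolute log2 fold change of at least 1, and 545 and 251 at an adjusted p below 0.01. The last 2 are stricter by construction, and with no filter 33539 genes were tested; for the others the cause was not tested. Leaving out a library gave 730 to 1326 higher and 423 to 841 lower genes, with fewer libraries. DESeq2 called 1781 and 1345 and limma on log2(FPKM + 1) 1194 and 883, and 99.1% and 83.4% of the genes called by edgeR were also called there, all in the same direction.

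Gene lists past the threshold, 13 of 24, became 6 at a mean FPKM of at least 5 (the RNA polymerase I, integrated stress, unfolded protein, NF-kB, extracellular matrix and mitochondrial lists no longer passed, and the interferon list had too few members left), 8 for limma at that filter, 0 with an estimated correlation, and 9 to 14 without a library; fry called 12, without RNA polymerase I, NF-kB, extracellular matrix and mitochondrial genes and with p38 MAPK, stemness and thyroid genes added. Annotated terms, 32, became 0 with an estimated correlation, 441 with no filter, 316 for limma with no filter, 8 at a mean FPKM of at least 5 with edgeR and 8 with limma, 20 for limma without the trend, and 25 to 67 without a library. The cause was not tested. An alternative chosen after the result was seen left out genes with a heptamer site or without an annotated 3′ UTR: of 9468 genes 1060 were higher and 758 lower, and 10 of 22 lists passed. Genes with only a hexamer stayed in. Set tests were not run for DESeq2 and the linear model without moderation. Over the alternatives that keep all libraries, named genes stayed on their side of the threshold in 1692 values and were weaker in 174, and lists did in 383, with 26 stronger and 15 weaker.

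With the replicate number as a replicate block, 1517 genes were higher and 1125 lower, POLR1F was at -2.31 and F2R at -1.19, 13 lists and 36 terms passed, and no list changed side. After removal of the group means, libraries of the same number correlated at 0.293, 0.0157 and 0.274. As 2 of 3 pairs lay above 0.1, the numbers were not treated as pairs. Along principal component 2 of the libraries, replicates 1 and 3 lay at 14.9 and -26.7 in NC. In siPOLR1F they lay at 24.5 and -15.9, and replicate 2 lay between them in both groups. The low correlation of replicate 2 is therefore weak evidence against pairs. All 6 libraries correlated best with the library of their own number, a hint from the data and not the design. A difference shared by libraries of the same number was not ruled out. In the simulated counts 30% of changes of -0.5 and 56% of changes of 0.5 were recovered. Only 50 genes were changed there at each size, with 126 calls in all, whereas 17.2% of genes were called in the data. Adjustment is stricter where fewer genes change, so these shares do not measure how many small changes passed unseen here.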

Other observations

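Further annotated terms, picked here after their values were seen, were called higher in siPOLR1F, although most of their members did not pass the edgeR test. The camera test with a preset correlation placed the SWI/SNF complex (26 genes, 8 rose; adjusted p = 0.0178) and histone methyltransferase complexes (25 genes, 12 rose; adjusted p = 0.0178) higher, beside the Cajal body, a nuclear site of small RNA maturation (56 genes, 16 rose and 1 fell; adjusted p = 0.00487). A term for positive regulation of stem cell population maintenance was higher as well (41 genes, 13 rose and 2 fell; adjusted p = 0.00336). All 4 terms had an adjusted p = 0.992 with an estimated correlation.

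Of the tests that follow, those on the 2 heptamers and on the splits of the libraries were chosen after the result was seen. For F2R and the KRAB zinc finger genes the prediction was written before the test. GGAGAAA, the heptamer ranked first among those that go with a rise, was tested first, with a median difference of 0.0381 for the octamer in the 3′ UTR; TCGGAGA was taken up after the scan placed it second.

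Genes with TCGGAGA in the 3′ UTR were higher in siPOLR1F, with a coefficient of 0.143 (SE 0.0177) beside UTR length and GC content, 8.07 times its SE against at most 4.40 in 20 scans of permuted genes, so length and GC content did not account for it. TCGGAGA is the site for a seed in the sense strand of a widely sold control siRNA. The labels do not say which siRNA was used. The site for the antisense strand of that control siRNA, TGTCACG, ranked 75 from the highest of 16185 heptamers scanned. Its coefficient was 0.0586 (SE 0.0148), a ratio below the permuted maximum of 4.40. That maximum is taken over all heptamers of a scan, which is too strict for a site set by the siRNA sequence. Falling below it therefore does not speak against a rise of genes with TGTCACG. The values that follow are for TCGGAGA. The median log2 fold change was 0.172 above that of genes without a site for the octamer in the 3′ UTR (69 genes), 0.139 for the heptamer (173 genes) and 0.0333 for the octamer in the 5′ UTR (permutation p = 0.415), but 0.223 for the octamer in the coding sequence (279 genes), so the 3′ UTR was not favoured over coding sequence. Genes with TCGGAGA in the coding sequence and no hexamer of it in the 3′ UTR stood in the scan as genes without the heptamer, since coding sites were not scanned. Unlike the differences above, theirs was adjusted for coding length and GC content, octamers included. On that measure their median lay 0.110 above that of genes without a site (750 genes, permutation p = 1.00e-05, the smallest possible). This is consistent with the control siRNA lowering these transcripts in NC, which would place part of the genes called higher outside the response to POLR1F loss: 21.6% of the higher genes hold the heptamer in the coding sequence or 3′ UTR, against 5.03% of the lower genes.

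CCGACTT was taken from the scan, where it ranked first among the heptamers that go with a fall. Its ratio to the SE was -6.42, against -4.59 at the lowest in the permuted scans. Genes with CCGACTT in the 3′ UTR were lower, with a coefficient of -0.120 (SE 0.0186) beside UTR length and GC content, so these did not account for it either. POLR1F itself holds CCGACTT once, as an octamer in its coding sequence; of 3874 genes of like length 10.2% hold the heptamer and 1.32% the octamer. Genes with CCGACTT in the coding sequence and no hexamer of it in the 3′ UTR likewise stood in the scan as genes without the heptamer. With adjustment for coding length and GC content, octamers included, their median lay -0.0799 from that of genes without a site (485 genes, permutation p = 1.00e-05, the smallest possible). Without adjustment, and whatever the 3′ UTR held, the heptamer in the coding sequence gave -0.0361 (465 genes, permutation p = 0.00439). The octamer there gave -0.0424 (50 genes, permutation p = 0.263). This is consistent with the POLR1F siRNA lowering other transcripts through its seed, and leaves open whether the fall of such genes follows from POLR1F loss. The annotated F2R transcripts hold 0 copies of the heptamer, which had been set beforehand as the bound against seed pairing with F2R, but that bound was too narrow: F2R has a hexamer in the 3′ UTR, and 15.7% of genes with such a hexamer were lower against 7.19% of those without (12.5% and 11.9% were higher). That hexamer, CGACTT, is part of CCGACTT and of CGACTTA, which ranked 2 for a fall in the same scan. These shares are therefore not independent of the scan. The median of genes with the hexamer differed by -0.0275, not tested by permutation and far smaller than the -1.18 of F2R. But a median does not bound a single gene. Pairing of the POLR1F siRNA seed with F2R could therefore not be told apart from an effect of POLR1F loss.

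The rise of KRAB zinc finger genes was not confined to members with TCGGAGA or its hexamer. The 130 members without a hexamer of it had a median 0.177 above that of other genes without one (permutation p = 1.00e-05, the smallest possible). The 91 members with a hexamer or longer site lay 0.221 above other genes with such a site. The draws were of genes, as if family members were independent. Camera gave the term an adjusted p = 0.974 with an estimated correlation. Genes with GGAGAAA, which shares the bases GGAGA with TCGGAGA and ranked first in the scan, were not left out. The control siRNA acting through such sites was therefore not ruled out. Whether POLR1F loss raises this family was not tested by other means.

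The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. As many genes as the real division (2333) were called in 1 of the 10, itself, and the highest of the others was 1 gene. The other divisions mix the groups, so any difference between NC and siPOLR1F widens the spread within each side. This lowers their gene counts, which therefore do not show how many genes would be called without a group difference. As many lists (13) were called in 2 of the 10, with a highest other of 16, and as many terms (32) in 5, with a highest other of 116, where NC 1, NC 3 and siPOLR1F 2 stood against the rest. A division across the groups that calls more terms points to a structure of the samples, or to the preset correlation of 0.01, which lies below the estimated one in some lists (0.496 for ribosome biogenesis) and above it in others (-0.0207 for p38 MAPK), and these were not tested apart. Cholesterol synthesis kept a camera adjusted p of 2.42e-06 or less in its 24 alternatives, which do not include the estimated correlation (adjusted p = 0.438).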
